A study of Mus musculus with 2 samples.

How the data were processed

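Chromatin immunoprecipitation followed by sequencing (ChIP-seq) of the transcription factor EBF1 and a matched input library were measured in splenic B cells of adult C57BL/6 mice. Per the labels' protocols, cells carrying CD43, AA4.1, CD4, CD8 or CD9 were removed with magnetic beads, and about 97% of the remaining cells were B220 positive. Of those, about 92% were CD23 positive with intermediate CD21, the surface phenotype of mature follicular B cells. The cells were fixed with 1% formaldehyde for 10 min and sonicated to fragments of about 200 bp. The ChIP sample was precipitated with 4 µg of a rabbit polyclonal antibody against mouse EBF1. Libraries were built from 10 ng of DNA with 15 PCR cycles, and fragments of 200 to 300 bp were taken from a gel.

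Each group held 1 library, EBF1 ChIP replicate 1 and Input replicate 1, numbered in accession order. The read files the authors deposited list 1 aligned read per line with its position and strand, without any value to normalise. Every read was 35 bp long. Each combination of chromosome, strand and 5′ position occurred once in each library. Yet ChIP reads filled up to 91.3% of the 300 positions over both strands of a peak. This argues against repeats never having been present, so repeated positions had probably been collapsed before deposit. The build is mm8 and the tool HOMER is named, per the submitters' processing notes. The aligner, the read filter and the handling of repeated reads are not given in the sources used here.

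The peak list the authors deposited holds a score per peak, the peak caller's own value, with no header to define its scale. Each peak was 150 bp long and every score was at least 5. How the score was calculated, and whether the input library was its control, are not given in the sources used here. The score is the authors' value and was used only to describe, rank and filter peaks within this list. It was treated as a score, although a fold over input had been planned for ranking.

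Reads in each peak were recounted from the deposited reads. The 5′ end of each read was moved 100 bp towards its 3′ end, and a read was counted when the moved position lay between the start and end of the peak. The ChIP to input ratio was divided by 1.06, the ratio of the 2 libraries' reads on chromosomes 1 to 19, X and Y. Ratios carry an exact conditional binomial (Clopper-Pearson) 95% interval, shares an exact Clopper-Pearson 95% interval and peak densities an exact Poisson 95% interval. All intervals, and the floor of 3 counts used where a library held 0 reads, cover counting error only (a fold against the floor leaves out the error of the ChIP count), since PCR reads without molecular identifiers are not independent molecules. With 1 library per group there is no replicate check, no p-value is given, and every comparison is between these 2 libraries. The recount uses the same reads from which the peaks were called, so ratios within peaks are raised by that selection. A peak of 150 bp offers 300 positions over both strands, which caps the count of reads per peak.

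Covered length was the number of 1 kb bins with at least 1 input read. Ratios outside peaks used 1 kb bins at least 2 kb from any peak, and 1 Mb windows needed at least 2000 input reads. Clusters joined peaks whose centres lay within 10 kb of the next, and their share was set against 100 random placements of the same peaks on the same chromosomes in bins with input reads. Enriched bins outside the peaks were 1 kb bins with at least 20 ChIP reads and a scaled ratio of at least 5. The same count with the libraries exchanged served as background. Strand cross-correlation was computed on chromosome 1 in steps of 5 bp, for distances of at least 60 bp. Peaks whose 1 kb bin held at least 50 input reads are called high-input peaks. This limit was set after the data were examined.

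The named peaks follow a rule fixed before the data were examined. It takes the 15 peaks with the highest score among those with at least 20 ChIP reads, the 5 peaks with the most ChIP reads and the 3 densest clusters, taken as those with the most peaks. Gene names were not attached to peaks, because the gene table at hand describes another build. The share of peaks near transcription starts, the planned gene lists, the genes planned to be named, and the EBF1 motif were therefore not analysed here.

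Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The ratio and its interval were tested on simulated data with the 7424 peaks and the depths of these libraries, in 20 draws. Peaks planted with no enrichment were called above input in 0.358% of cases. The share called was 3.95% at a planted ratio of 2, 27.7% at 4, 67.6% at 8 and 91.7% at 16. For sites not selected on their reads, the depth thus shows most only from a ratio of about 8 upward. The listed peaks were called on the same reads, and the simulation left that selection out. Its shares therefore do not give the error rate of calls among the listed peaks. Alternatives fixed before the data were examined covered the score limit, merging of nearby peaks, repeated positions, the distance by which reads were moved, background scaling, the window around the peak centre, the cluster distance and the limits for bins outside peaks.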

Results

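EBF1, a transcription factor required for the B cell lineage, was mapped by ChIP-seq in mature follicular B cells from mouse spleen to find where it is bound in these cells. The data were 1 EBF1 ChIP library of 24354888 aligned reads and 1 input library of 23053279 aligned reads, together with the authors' list of EBF1 peaks. On chromosomes 1 to 19, X and Y the libraries held 24337709 and 23033569 reads, and a covered 1 kb bin held a median of 10 ChIP and 9 input reads. A count of 0 allowed up to 0.123 RPM in the ChIP library and 0.130 RPM in the input. There were no replicates, so values below carry counting error at most. All positions are in the mm8 build.

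The list held 7424 EBF1 peaks, of which 7415 lay on the assembled chromosomes, 9 on unplaced contigs and 0 on chromosome Y. Scores ran from 5.00 to 124.6, with a median of 6.07 and an upper quartile of 8.33, so most peaks lay close to the lowest score in the list. A score of at least 10 was reached by 1404 peaks (18.9%), a score of at least 20 by 462 and a score of at least 50 by 51. The median peak held 12 ChIP reads and 1 input read, and 1948 peaks held 0 input reads.

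EBF1 ChIP reads were enriched in the peaks as a whole. The peaks took 0.595% of the ChIP reads (0.592 to 0.598%) and 0.0590% of the input reads (0.0580 to 0.0600%), measured the same way over 1113.6 kb. The scaled ChIP to input ratio was 10.1 (9.92 to 10.3). Peaks in the top score quartile reached a ratio of 20.2 (19.5 to 20.8), and the lower 3 quartiles reached 6.99, 5.90 and 6.09, from the higher scores to the lower. Taken 1 by 1, 6430 peaks (86.6%) had an interval above 1, and 2842 had an interval above 2. The peaks were called on the same reads, so these counts are no independent check of the list. The call was made for 99.8% of peaks in the top quartile and 71.9% in the lowest, where the median peak held 9 ChIP reads. The ratio fell to 3.67 when reads were counted in 1 kb around the peak centre, and the share of ChIP reads rose to 1.46%.

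ChIP signal was narrow around the called positions. Those positions were called on the same reads, so a maximum at the centre follows from that choice and is no independent check. For this profile the 5′ ends were moved by 50 bp, a distance chosen after the data had been seen. Over the 7361 peaks on chromosomes 1 to 19 and X outside high-input bins, ChIP read density within 40 bp of the centre was 7.39 RPKM (reads per kb, scaled to library size), against 0.732 at 800 to 1000 bp, a ratio of 10.1. The input had 0.488 RPKM at the centre and 0.503 in the flanks, a ratio of 0.971. Between them the input dipped, to 0.377 RPKM at -100 to -80 bp and 0.392 at 80 to 100 bp. The ChIP profile was 120 bp wide at 50% of its height above the flank. The distance between strands with the highest correlation on chromosome 1 was 90 bp in the ChIP library and 115 bp in the input, against 95 bp and 130 bp on chromosome 19.

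**Figure D1:**
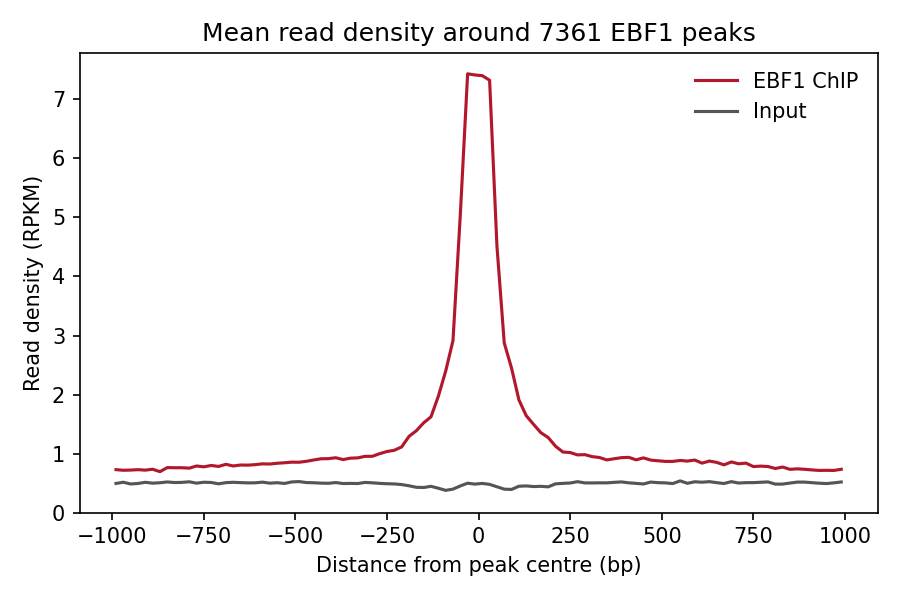
Mean read density in RPKM (vertical axis) against distance from the peak centre in bp (horizontal axis), in bins of 20 bp over 7361 peaks, with 1 line per library. The 5′ ends of reads were moved by 50 bp. The EBF1 ChIP line rises from 0.732 in the flanks to 7.39 at the centre, while the input line runs from 0.503 in the flanks through dips of 0.377 and 0.392 to 0.488 at the centre.

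The highest-scoring peak lay on chromosome 6 at 94483781 to 94483930, with a score of 124.6. It held 191 ChIP reads and 0 input reads, at least 60.3-fold above the floor of 3 input counts. The next was on chromosome 11 at 51599881 to 51600030, with a score of 114.7, 189 ChIP reads and 0 input reads (at least 59.6-fold). The third, on chromosome 5 at 124233941 to 124234090, had a score of 109.7 and held 225 ChIP and 2 input reads, a ratio of 106 (29.1 to 885). A peak on chromosome 1 at 95308711 to 95308860 scored 98.4, with 198 ChIP reads and 0 input reads (at least 62.5-fold). On chromosome 18, the peak at 10918481 to 10918630 scored 95.3 and held 267 ChIP and 4 input reads, a ratio of 63.2 (24.4 to 234). The peak on chromosome 8 at 73794621 to 73794770 scored 95.1 with 196 ChIP reads and 1 input read, a ratio of 185 (32.9 to 7364).

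Scores of the other 9 peaks among the top 15 ran from 90.1 down to 67.7. Chromosome 7 held 3 of them, at 28497741 to 28497890 (204 ChIP and 3 input reads), at 24154411 to 24154560 (228 and 2) and at 81982851 to 81983000 (178 and 4). Chromosome 14 had peaks at 64297831 to 64297980 (146 ChIP and 0 input reads, at least 46.1-fold) and at 55622191 to 55622340 (176 and 3). Chromosome 5 had further peaks at 122094541 to 122094690 (208 ChIP and 2 input reads) and at 125341781 to 125341930 (190 and 1). The remaining peaks were on chromosome 2 at 30263901 to 30264050 (169 ChIP and 0 input reads, at least 53.3-fold) and on chromosome 11 at 109242161 to 109242310 (180 and 3). For the 5 of the 15 peaks with 0 input reads, the lower bound of the exact interval, which includes the error of the ChIP count, ran from 37.0 to 50.3. With so few input reads the order of these peaks by ratio is not resolved at this depth. ChIP reads filled at least 50% of the 300 positions in 34 peaks, and up to 91.3% in 1 of them, so the counts of the strongest peaks are lower limits.

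The peaks with the most ChIP reads were of different kinds. On chromosome 17, peaks at 39452221 to 39452370, at 39453181 to 39453330 and at 39456341 to 39456490 held 274, 268 and 256 ChIP reads, but also 182, 121 and 121 input reads. Their ratios were 1.42 (1.18 to 1.73), 2.10 (1.69 to 2.62) and 2.00 (1.61 to 2.51). ChIP reads filled 91.3%, 89.3% and 85.3% of the 300 positions in these 3 peaks. The cap on positions therefore pushes their ratios down, which the intervals leave out, and the pooled ratios of high-input peaks below include them. The other 2 of the 5, on chromosomes 18 and 7, were the peaks at 10918481 (ratio 63.2) and 24154411 (ratio 108, 29.5 to 896) already named. In all, 54 peaks (0.727%) lay in 1 kb bins with at least 50 input reads. Their ratio was 1.99 (1.88 to 2.10), against 11.5 (11.3 to 11.7) for the other peaks. The peak on chromosome 1 at 129342151 to 129342300, chosen after its values were seen, stood apart among the 54, with a score of 45.8, 110 ChIP reads and 1 input read, a ratio of 104 (18.3 to 4149). Without it the ratio was 1.94 (1.83 to 2.04).

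Peak density differed between chromosomes. The autosomes held 7326 peaks, 3.20 per covered Mb (3.12 to 3.27). Density was highest on chromosome 11, at 5.71 (5.29 to 6.16), followed by chromosome 19 at 4.86 (4.31 to 5.47), chromosome 17 at 4.70 (4.26 to 5.18) and chromosome 7 at 4.13 (3.79 to 4.50). It was lowest among autosomes on chromosome 14, at 2.01 (1.75 to 2.29), and chromosome 3, at 2.05 (1.83 to 2.29). Chromosome X held 89 peaks, 0.624 per covered Mb (0.501 to 0.768), which was 5.12-fold lower (4.16 to 6.38) than the autosomes. Input reads per covered kb on X were 0.883 of the autosomal value. The highest score on X was 24.0, and 14 X peaks had a score of at least 10.

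**Figure D2:**
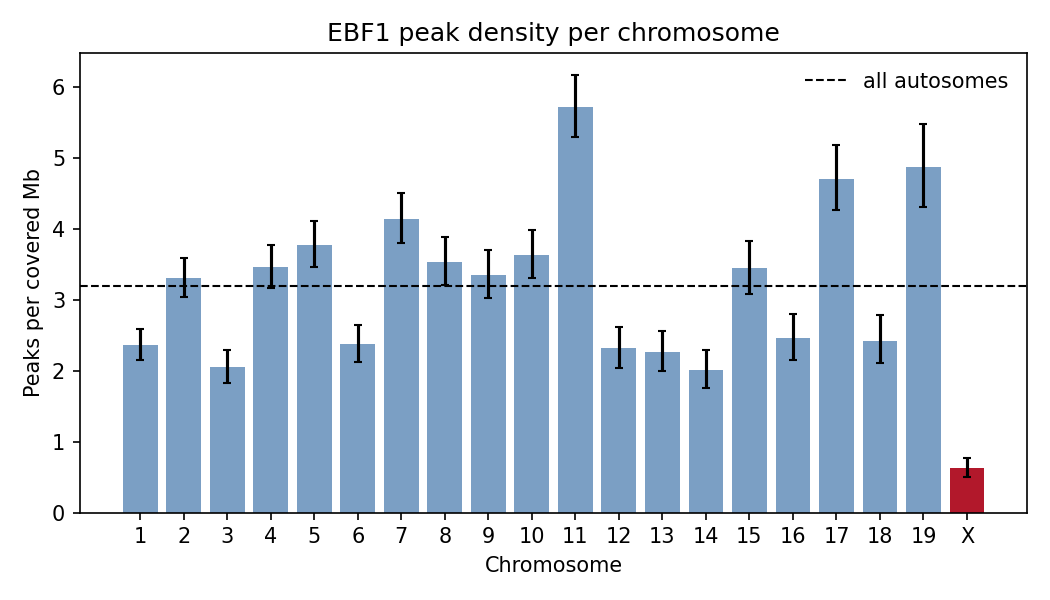
EBF1 peaks per covered Mb (vertical axis, from 0) for each chromosome (horizontal axis), as bars with exact Poisson 95% intervals and a dashed line at the autosomal density of 3.20. Chromosome 11 stands highest at 5.71 and chromosome X, in red, lowest at 0.624.

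Within chromosomes the peaks gathered in some regions and were missing from others. Of 2532 windows of 1 Mb, 964 (38.1%) held 0 peaks, while the window on chromosome 10 from 80000001 to 81000000 held 44 and the one before it, from 79000001 to 80000000, held 35. Regions with more peaks also had more ChIP reads relative to input outside the peaks. At least 2 kb from any peak, the median scaled ratio was 0.825 in windows with 0 peaks, 0.946 with 1 to 2, 1.05 with 3 to 5, 1.15 with 6 to 10 and 1.28 with 11 or more. Spearman's rho between peaks and this ratio was 0.76 over all windows and 0.76 over the 2383 autosomal windows. These are windows of 1 genome in 1 pair of libraries, not independent replicates. By chromosome the ratio outside peaks was 1.08 on chromosome 11 and 0.844 on X.

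**Figure D3:**
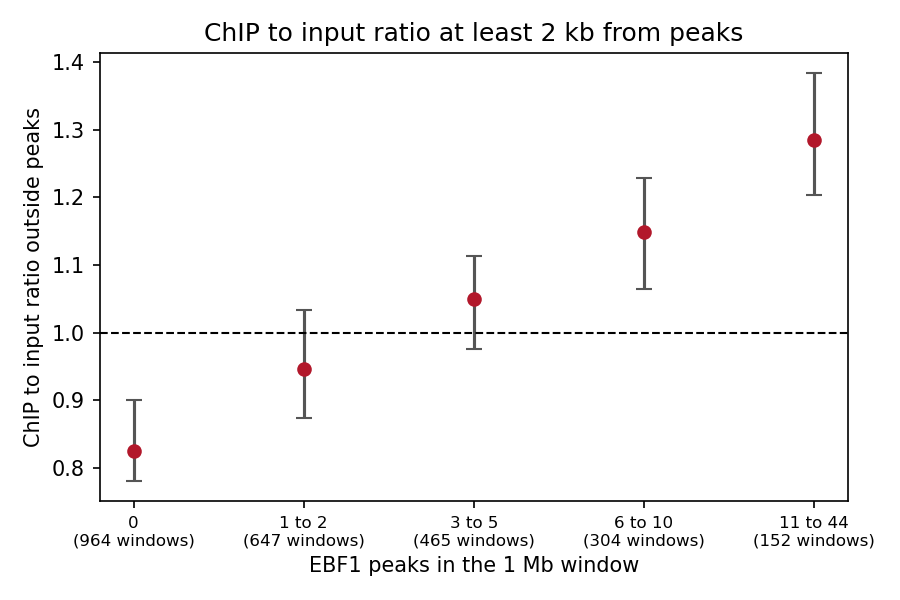
Scaled ChIP to input ratio at least 2 kb from any peak (vertical axis) in 1 Mb windows grouped by their number of EBF1 peaks (horizontal axis), with points at the median and bars from the lower to the upper quartile and a dashed line at a ratio of 1. The median rises from 0.825 in the 964 windows with 0 peaks to 1.28 in the 152 windows with 11 to 44 peaks.

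EBF1 peaks lay near one another more often than random placement gave. Of 7415 peaks, 2108 (28.4%, 27.4 to 29.5%) had another within 10 kb. The mean of 100 random placements was 6.51% and the highest 7.26%, so the observed share was 4.37 times the mean. The placements were even over the covered bins of each chromosome. The regional differences described above thus raise the observed share too, and were not separated from grouping within 10 kb. There were 888 clusters of at least 2 peaks and 27 of at least 5. The observed share was 20.3% within 5 kb, against 3.29% at random, and 59.8% within 50 kb, against 28.0%. Among the top 50% of peaks by score, 21.4% had such a neighbour within 10 kb, against 3.40% at random.

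The 3 clusters with the most peaks differed in their input. The cluster on chromosome 10 at 79544451 to 79571270 held 11 peaks with scores up to 32.5. Its peaks had a ratio of 10.0 (6.51 to 16.1), its whole interval 2.99 (2.63 to 3.41), and its input 11.7 reads per kb. The cluster on chromosome 11 at 3025551 to 3081460 held 24 peaks with scores up to 8.14, and its interval had 245 input reads per kb. Its peaks had a ratio of 1.80 (1.67 to 1.94) and its whole interval 1.22 (1.19 to 1.24). High-input bins held 23 of its 24 peaks. The cluster on chromosome 1 at 90061371 to 90091540 held 13 peaks with scores up to 6.93, 9 of them in high-input bins. Its peaks had a ratio of 2.42 (1.97 to 2.99), its whole interval 1.57 (1.47 to 1.67), and its input 52.1 reads per kb.

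ChIP enrichment was also seen outside the listed peaks. In total 2005 bins of 1 kb, in 1988 separate places, had at least 20 ChIP reads and a ratio of at least 5, against 465 bins when ChIP and input were exchanged. With at least 30 reads the counts were 307 and 6. The exchanged count assumes that both libraries vary alike, so local enrichment was not separated from the regional differences in ChIP background described above. The bins with the most ChIP reads were on chromosome 17 at 87174001 to 87175000, with 75 ChIP and 8 input reads (ratio 8.87, 4.28 to 21.3), and on chromosome 7 at 44683001 to 44684000, with 75 and 10 (ratio 7.10, 3.65 to 15.4). Bins were picked for their ratio, so both values are raised by that choice. The count depended on the limits and was 183 with a ratio of at least 10, 376 when at least 5 input reads were also required, 737 in bins of 500 bp and 3031 with background scaling. At a ratio of 5, the limit on input reads also raises the ChIP reads needed above 20. The count of 376 is therefore no check on bins with few input reads.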

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

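The ratios of unplaced contigs and of the mitochondrial genome were chosen after the data had been seen. Outside the 9 peaks that lie on them, reads on unplaced contigs entered no comparison, and they stood above input. The ChIP library had 12967 and the input 11860, a scaled ratio of 1.035 (1.01 to 1.06). By chromosome the ratio outside peaks ran from 0.844 on X to 1.08 on chromosome 11. The contigs thus lay within the range of the background. Reads on the mitochondrial genome, also unused, stood below input at 4007 against 7810, a scaled ratio of 0.486 (0.467 to 0.504).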

How the results depend on the processing

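The settings with reads moved by 50 bp, corrected for occupied positions, or without high-input peaks were chosen after the data had been seen, and the others before. Counts of peaks or bins were taken as moved beyond 1.5 times the main count, and other values outside their 95% interval or, for the strand distance, by any change. By these measures 22 values moved and 20 did not, and no direction turned. Peaks with an interval above 1 numbered 5464 with reads not moved, within that limit. The ratio within peaks was 8.91 with reads not moved, 11 with reads moved by 50 bp, 10.7 with background scaling, 9.91 in 200 bp and 3.67 in 1 kb around the centre, 10.8 corrected for occupied positions and 11.5 without high-input peaks. The share of ChIP reads in peaks was 0.513% with reads not moved, 0.660% with reads moved by 50 bp, 0.772% in 200 bp, 1.46% in 1 kb and 0.578% without high-input peaks. Taking the top 50% by score left 3712 peaks by construction, and asking for an interval above 2 left 2842. Enriched bins outside peaks numbered 3031 with background scaling, 183 at a ratio of 10, 737 in 500 bp bins and 376 with at least 5 input reads. The ChIP strand distance was 95 bp on chromosome 19. The share of peaks with a neighbour was 20.3% at 5 kb, 59.8% at 50 kb and 21.4% for the top 50% by score. The cause of these shifts was not tested. The density on X relative to autosomes, 0.195, stayed between 0.162 and 0.221. Collapsing repeated positions and asking for a score of at least 5 moved nothing because the files already meet both, so they say nothing about stability. Depth limits the calls, since only 67.6% of simulated peaks at a ratio of 8, drawn without selection, were called. No paired analysis was possible because each group held 1 library and the only shared number was given in accession order. Alternatives for transcription starts, gene lists and the motif were not run.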

Other observations

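The tests chosen only after the result was seen are all those of chromosome X except the matched windows, all those of chromosome 12, and the measure of input reads per mappable position. That measure takes positions already read on 1 strand or in 1 library and counts how often an input read of another kind starts on the same 35 bp. It does not depend on how much of a region can be mapped, and it is given relative to the median of 2373 autosomal 1 Mb windows with at least 3000 input reads, whose middle 90% ran from 0.853 to 1.22.

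A stretch of low read density lay on distal chromosome 12, from 113750001 to 116500000. Among windows of 250 kb in which at least 0.8 of the 1 kb bins held an input read, it was the longest run at or below 0.8 of the chromosome's median density, with 11 of the 9613 windows examined. The next longest such run covered 4. Without the limit on covered bins 7 runs were longer, up to 18 windows on chromosome 7 from 19250001 to 23750000, where 29.6% of bins held a read. At the near edge on chromosome 12, input density fell from 531 reads in the 40 kb up to position 113880000 to 28 in the next 40 kb. The ratio was 0.0527 (0.0347 to 0.0771). The edge was placed at the largest fall, so this ratio is extreme by choice, which its interval leaves out. ChIP reads fell from 632 to 20. Density was 0.288 of the median in the window from 114000001 and rose to 0.768 in the window from 115250001. It was then 0.560, 0.555, 0.590 and 0.740. The stretch held 1 EBF1 peak.

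Sequence that cannot be mapped was 1 explanation weighed for this stretch. Between the edge and 115000000 the number of input reads per mappable position was 0.5139 of the autosomal median (0.378 to 0.683), lower than in any of the 2373 windows, which argues against unmappable sequence as the whole cause there. In the rest of the stretch the number of input reads per mappable position was 0.9024 (0.770 to 1.05), so lost mappability may account for that part. As a hypothesis, many cells may have lost DNA beside the edge, as in V(D)J recombination of the immunoglobulin heavy chain locus on distal chromosome 12, although the overlap of the stretch with that locus was not checked in this build. Spearman's rho of density with distance was 0.6727 over the 10 windows wholly past the edge (0.4 over all 11, of which the first spans the edge), as such a loss would give, but the rise lay in the first 6 of the 10, graded mappability would also give it, and an inherited deletion in these mice was not tested.

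The low peak density on chromosome X was weighed against 3 explanations. Chromosome X held 22 peaks with at least 20 ChIP reads (13.8 to 33.3), and fewer mappable reads would leave 95.1 (51.4 to 194 when single autosomes were used). Windows matched to X on the ratio outside peaks gave 147.5 peaks in all (136 to 158), above the 89 observed (71.5 to 110). Without matching, X lay 5.12-fold below the autosomal density. The matched group with the highest ratios had no upper limit. Autosomal windows ran higher there (median over all windows 0.968, against 0.822 on X), which raises the expected number. Low ChIP background may thus account for much of the deficit, and whether it accounts for all of it cannot be told. Input reads per mappable position on X had a median of 0.972, where 1 X copy per cell would give about 0.5. A signal of 50% at every X site, as if 1 of 2 copies were bound (the sex of the mice is not given in the labels), would leave 44.78 peaks with at least 20 ChIP reads at the mean autosomal density, above the interval of the 22 observed, but 21.8 to 103 with single autosomes. Such a signal goes against the mean autosomal density, but with a site density as low as that of some autosomes it cannot be told apart from a lower number of sites.

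The high-input peaks were weighed last. The 426 high-input bins away from peaks had a ChIP to input ratio of 0.8714 (0.860 to 0.883), but bins picked for high input and distance from peaks would give such a ratio whatever raised their input, so collapsed multi-copy sequence stays open. The 54 high-input peaks held a median of 28.92 ChIP reads above scaled input, against 10.9 for other peaks. The peak on chromosome 1 at 129342151, singled out after its values were seen, had a ratio of 104 (18.3 to 4149), and the other 53 had a pooled ratio of 1.94 (1.83 to 2.04). For those 53, EBF1 may be bound at some copies of a repeat, but the peaks were selected for an excess, so binding and uneven recovery of repeats cannot be told apart.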
